A study of Mus musculus with 96 samples.

How the data were processed

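RNA was sequenced from 6 tissues (cortex, cerebellum, striatum, liver, brown fat and white fat) of the same 16 mice, giving 96 libraries. Per the labels, the mice belong to 2 lines, one carrying a deletion and the other a duplication of the segment from Slx1b to Sept1 on mouse chromosome 7, the segment matching human 16p11.2. Each line gave 4 carriers and 4 wild types, 2 males and 2 females in each group. The lines differ in strain name (B6129S-Del(7Slx1b-Sept1)4Aam/J and B6129S-Dp(7Slx1b-Sept1)5Aam/J), stock number, litter label and age. The age was 59 days for the females and 68 days for the males of the duplication line. In the deletion line it was 53 days, except for the wild-type females at 50 days. Line, litter label and age cannot be separated, so carriers were compared with the wild types of their own line. Among females of the deletion line, age still goes with genotype (50 days in wild types and 53 in carriers).

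Per the labels' protocols, total RNA was extracted with TRIzol, strand-specific libraries were made with dUTP, and the libraries were sequenced as read pairs with ERCC spike-ins of Mix1 or Mix2 added. FastQC, Picard, GSNAP, bedtools and the build GRCm38 are named, per the submitters' processing notes, with no role or order. The authors deposited 1 table per tissue of whole-number counts per gene, which the names of the deposited tables describe as sense-strand counts. How reads that match several places were counted is not given in the sources used here, so counts of pseudogenes, retrocopies and other near-identical copies are uncertain. The tables hold 39017 gene rows and 92 ERCC rows. Symbols, positions and gene classes came from GENCODE M21 (GRCm38), which held 37607 of the gene rows (96.4%). ERCC rows took between 0.0910 and 10.3% of the counts of a library and were left out of library sizes and tests. All columns of the tables were used.

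Total gene counts per library ranged from 46831980 to 97740854 in cortex, 40227624 to 68261669 in cerebellum, 41279595 to 98988777 in striatum, 67034547 to 304686818 in liver, 39658492 to 96089236 in brown fat and 50037724 to 75032048 in white fat. The sex label matched Xist and Ddx3y in 96 of 96 libraries, although Xist stood at 79.9 CPM in striatum of deletion 2, a male.

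From the counts, each tissue was fitted with edgeR 4.0.16 (R 4.3.3) over its 16 libraries. The fit used TMM normalization, the filterByExpr filter (minimum count 10, minimum total count 15), 4 groups and sex as terms, and the robust quasi-likelihood test. The contrasts were deletion minus its wild types, duplication minus its wild types, the reciprocal contrast (the duplication effect minus the deletion effect) and wild types of the duplication line minus wild types of the deletion line. The p-values were adjusted by Benjamini and Hochberg over the genes tested in the tissue, with a threshold of 0.05. Levels are given as CPM (counts scaled to a common library size) with TMM library sizes, as mean ± SD over 4 mice, and effects as log2 fold changes ± SE. Genes of the interval were counted apart from all others. For the interval, and for other fixed lists, a second adjustment was made over the list alone. The average over tissues was tested with limma 3.58.1 on 1 value per mouse, the mean over 6 tissues of log2 CPM (prior count 2). Differences of the interval effect between tissues were tested with an edgeR F test over all 96 libraries, with the mouse as a block. A total of 38 gene lists were tested with camera on voom values (preset correlation 0.01), with camera and an estimated correlation, and with fry, over 143 list and tissue pairs per line. In camera tests the interval genes were left out of the other lists and of the background.

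The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where an alternative is said to have been chosen later. The rule named every measured interval gene. Outside the interval, it took the 3 largest rises and the 3 largest falls per line and tissue among genes past the threshold. These needed a mean log2 CPM of 1 or more, a symbol that is not a Gm number, Rik clone, pseudogene or accession, and every carrier on the same side of the mean of its wild types. It also took up to 10 genes, by smallest summed rank of p, that passed in the same direction in 3 or more tissues of a line or passed in both lines in the same tissue. From each list whose test passed it took up to 4 members of smallest p, and members of fixed lists that passed over the list alone could be named as such. The alternatives were RLE size factors, no low-count filter, no sex term, fits of the 8 libraries of 1 line, pooled wild types, a replicate block, DESeq2 1.42.0, each sex alone, and leaving out each mouse in turn. Chosen after seeing the data were the fits without libraries that stood apart from the rest, with offsets for trends over GC content and length, and with protein-coding genes only.

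For the deletion against wild type, the edgeR, limma, camera (preset correlation) and between-tissue tests were checked on simulated counts with the means and library sizes of the real libraries. With 200 genes changed in the deletion group, edgeR recovered 73% of 1.5-fold and 90% of 2-fold changes in cortex, 7% and 50% in cerebellum, 16.2% and 54% in striatum, 3.1% and 46.9% in liver, 0% and 1% in brown fat, and 0% and 0% in white fat. Of unchanged genes edgeR called 5 in cortex, 3 in cerebellum, 5 in striatum and 0 in the other 3 tissues. In the duplication, where no gene was changed, it called 3 in cerebellum and 0 in the other 5 tissues. The limma test of the average over tissues recovered 57% and 90% and called 11 unchanged genes. The camera test called the 1 list raised by 1.3-fold and 0 of the other lists, and the test between tissues recovered 0 of 10 genes with a 2-fold and 10 of 10 with an 8-fold difference, and called 1 unchanged gene each time. The reciprocal and wild-type contrasts, DESeq2, fry and camera with an estimated correlation were not checked in this way. Genes were drawn independently of each other, so these checks do not show how the tests act on genes that move together between mice. In other splits of the real mice, camera called up to 70 lists (below).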

Results

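The data are RNA-seq gene counts of cortex, cerebellum, striatum, liver, brown fat and white fat from 16 mice of 2 lines. In the deletion line, 4 mice lacked 1 copy of the segment from Slx1b to Sept1, and 4 wild types came from the same line. In the duplication line, 4 mice carried an extra copy of that segment, and 4 wild types came from that line. Mice are named below by group and number: wild types 1 to 4 and duplication 1 to 4 in the duplication line, and wild types 5 to 8 and deletion 1 to 4 in the deletion line. Each group held 2 males and 2 females. A library held between 39658492 and 304686818 gene counts, with the extremes in brown fat and liver. Unless stated otherwise, effects are log2 fold changes ± SE from edgeR, levels are CPM as mean ± SD (n = 4 mice per group), and adjusted p-values run over all genes tested in the tissue.

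The comparison of deletion mice with their wild types asked how losing a copy of the segment changes its genes. In cortex, Prrt2, which encodes a presynaptic protein, fell by 1.19 ± 0.05, from 307 ± 15.5 to 135 ± 3.83 CPM (adjusted p = 2.09e-10). Kctd13, an adaptor of a ubiquitin ligase, fell by 1.06 ± 0.07, from 71.0 ± 4.10 to 34.1 ± 1.09 CPM (adjusted p = 4.8e-09). Mapk3, the kinase ERK1, fell by 0.97 ± 0.09, from 129 ± 14.4 to 65.7 ± 8.69 CPM (adjusted p = 3.19e-06). Taok2, a kinase of dendrite growth, fell by 0.96 ± 0.07, and the glycolytic enzyme Aldoa fell by 1.14 ± 0.07, from 1387 ± 84.4 to 631 ± 38.6 CPM. The largest fall in cortex was in Tbx6, a T-box transcription factor of the early mesoderm, at -1.61 ± 0.27. Of 37 interval genes measured in cortex (chromosome 7, 126689468 to 127218426), 36 had lower fitted values and 30 passed the threshold, with a median of -1.06, or 0.48-fold. Gdpd3, a lysophospholipase D, stood at 0.07 ± 1.4, and the small nuclear RNA gene Gm22747 at -0.11 ± 0.15. The median over measured interval genes was -1.04 in cerebellum, -0.91 in striatum, -0.76 in liver, -0.80 in brown fat and -0.55 in white fat. In white fat the quartiles were -0.97 and -0.31, against -1.13 and -0.99 in cortex. Some fat libraries held transcripts of other tissues (below), so a smaller median there does not show a weaker effect of dosage. The threshold was passed by 16 of 37 genes in cerebellum, 15 of 37 in striatum and 8 of 34 in liver, the last including Taok2 (-1.32 ± 0.12), Mapk3 (-0.84 ± 0.11) and Cd2bp2 (-0.81 ± 0.11), a splicing factor.

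In both fats edgeR called 0 of 35 interval genes lower, with 20 in brown and 15 in white fat at an unadjusted p under 0.05, while DESeq2 called 7 and 9. Of the interval genes on the list fixed beforehand, those past the threshold when adjusted over the list alone were 30 of 31 in cortex, 27 of 31 in cerebellum, 24 of 31 in striatum, 20 of 29 in liver, 13 of 29 in brown fat and 11 of 29 in white fat. In white fat Kctd13 fell by 1.17 ± 0.27, from 4.94 ± 0.957 to 2.19 ± 0.525 CPM (adjusted p = 0.388 over all genes and 0.00386 when adjusted over the list alone). Without deletion 2, the count of called interval genes was 24 in striatum and 14 in liver. In liver it was 4 without wild type 5, wild type 8 or deletion 3, and 5 without wild type 6, wild type 7, deletion 1 or deletion 4.

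The comparison of duplication mice with their wild types asked the mirror question. In cortex, Kctd13 rose by 0.68 ± 0.06, from 64.9 ± 6.40 to 104 ± 5.38 CPM (adjusted p = 6.26e-06), and Prrt2 by 0.66 ± 0.05, from 288 ± 12.1 to 455 ± 28.7 CPM. Asphd1, a predicted hydroxylase, rose by 0.87 ± 0.07, the zinc finger factor Maz by 0.82 ± 0.07, and Fam57b, a ceramide synthase of membranes, by 0.79 ± 0.06. Aldoa rose by 0.58 ± 0.07, from 1336 ± 122 CPM in wild types, and Coro1a, an actin regulator of immune cells and neurons, by 0.47 ± 0.07. Mapk3 rose by 0.42 ± 0.09, from 116 ± 4.58 to 155 ± 9.68 CPM, and missed the threshold (adjusted p = 0.0573 over all genes and 0.000279 when adjusted over the list alone). All 37 interval genes measured in cortex had positive fitted values and 23 passed the threshold, with a median of 0.65, or 1.57-fold. The medians were 0.59 in cerebellum, 0.53 in striatum, 0.55 in liver, 0.39 in brown fat and 0.56 in white fat. In brown fat the quartiles were 0.18 and 0.55, and some libraries of both fats held transcripts of other tissues (below). The smaller median there does not show a weaker effect of dosage. In cerebellum, 2 of 37 passed, the surface protein gene Sez6l2 (0.67 ± 0.08, adjusted p = 0.0106) and Pagr1a, a subunit of a histone methyltransferase complex (0.75 ± 0.09, adjusted p = 0.0106). Pagr1a overlaps Prrt2 on the same strand in the annotation, so its counts can hold reads of Prrt2.

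In the other 4 tissues edgeR called 0 interval genes in duplication mice, though with the replicate block it called 7 in striatum, and 0 in place of 2 in cerebellum. At an unadjusted p under 0.05 there were 21 in striatum, 19 in liver, 6 in brown fat and 15 in white fat, and DESeq2 called 7, 10, 0 and 7. Adjusted over the list alone, the genes past the threshold were 26 of 31 in cortex, 17 of 31 in cerebellum, 18 of 31 in striatum, 15 of 29 in liver, 0 of 29 in brown fat and 12 of 29 in white fat. The cerebellar count was 1 without duplication 2 and 0 without wild type 1, wild type 2, wild type 4, duplication 1, duplication 3 or duplication 4. It was 22 without wild type 2 of this line and wild type 5 and deletion 2 of the other, 13 with DESeq2 and 10 with offsets for GC content and length.

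**Figure D1:**
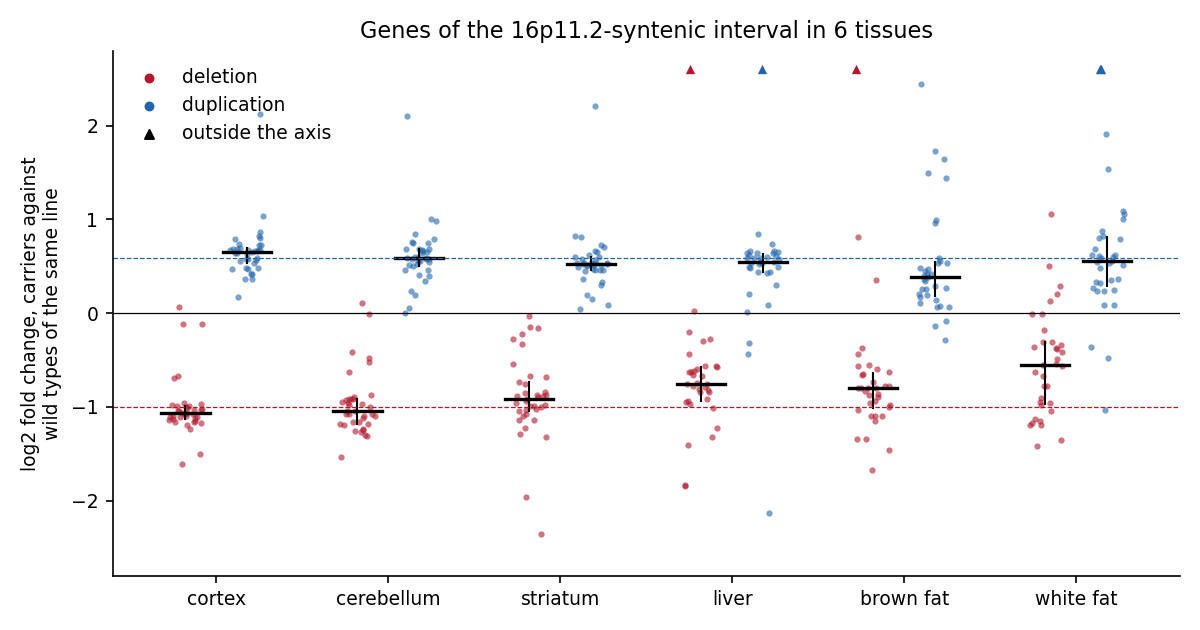
Log2 fold change of each measured interval gene (points) in each tissue, for deletion and duplication mice against their own wild types, with black bars for the median and quartiles, dashed lines at -1 and at the log2 of 1.5, and triangles for values outside the axis. Deletion medians lie between -1.06 in cortex and -0.55 in white fat, and duplication medians between 0.39 in brown fat and 0.65 in cortex. Some libraries of both fats held transcripts of other tissues, so their medians are less certain.

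**Figure D2:**
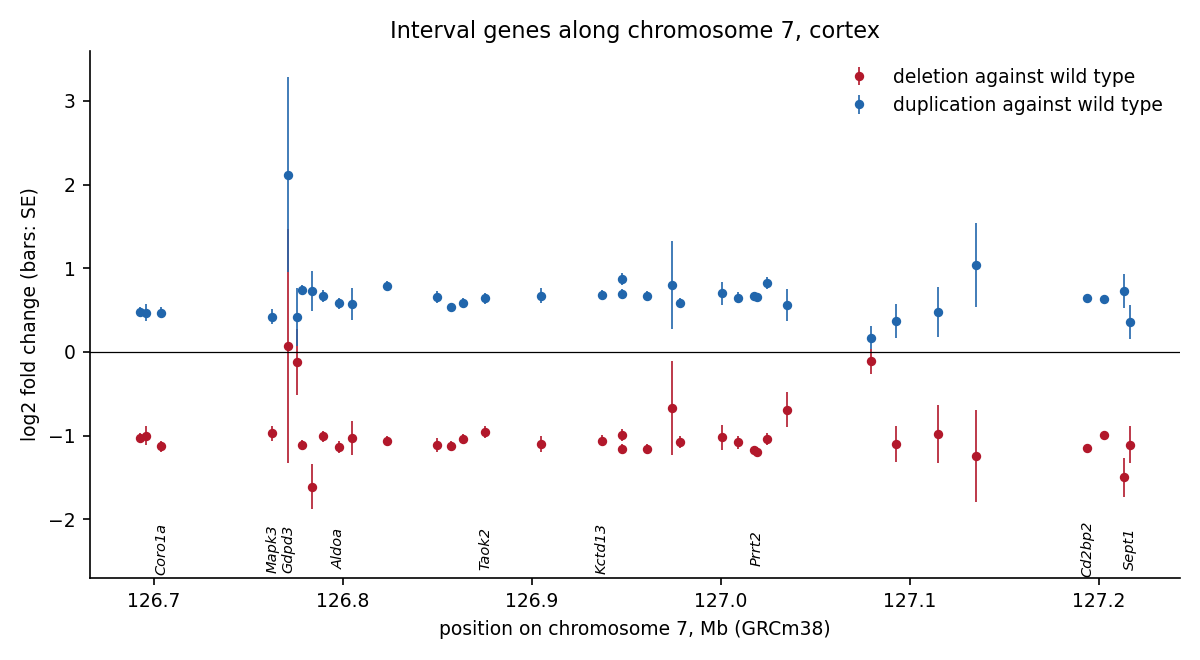
Log2 fold change ± SE in cortex of interval genes at their positions on chromosome 7, for deletion and duplication mice against their own wild types. Of the 37 genes, 36 lie below 0 in deletion mice and 37 above 0 in duplication mice.

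A test of the difference between tissues asked whether the interval effect varied. In deletion mice, Pagr1a fell by 1.17, 1.16 and 1.14 in cortex, cerebellum and striatum, and its effects in liver, brown fat and white fat were -0.56, -0.59 and -0.54 (adjusted p = 0.0482). Asphd1 also passed (adjusted p = 0.0482), but its effects in the 3 brain tissues were alike (-0.99, -1.18 and -0.98), and the test includes liver and both fats, where it was too low to be measured, so its p is not that of a difference between these values. Among genes with a mean CPM of 1 or more in every tissue, Pagr1a was the 1 gene called. These were 2 of 38 genes tested, and edgeR called 0 in duplication mice, where 5 genes had an unadjusted p under 0.05 and the lowest adjusted p was 0.240, for Coro1a and Qprt. DESeq2 was not run for this test. The count in deletion mice was 1 without deletion 4 and 0 without deletion 1, deletion 2 or any of wild types 5 to 8. In duplication mice it was 1 without duplication 2 or duplication 4 and 3 without duplication 3.

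Outside the interval, the gene Tyr (chromosome 7, 87427405 to 87493411), which encodes tyrosinase, the enzyme that starts melanin synthesis in pigment cells, separated the 4 deletion mice from the other 12 mice in every tissue. Its counts were 396 to 600 in cortex of deletion mice and 0 to 11 in cortex of the other 12 mice. The ranges were 291 to 666 against 0 to 3 in cerebellum, 50 to 401 against 0 to 10 in striatum, 28 to 104 against 0 to 2 in liver, 96 to 214 against 0 to 2 in brown fat, and 71 to 347 against 0 to 1 in white fat. The adjusted p was 6.53e-09 in cortex, 1.74e-06 in cerebellum, 0.00082 in striatum, 0.00398 in liver and 0.0167 in brown fat. In white fat it was 0.0697 with edgeR and 7.84e-11 with DESeq2. The call in brown fat was lost without any mouse of the line except deletion 2, with an adjusted p of up to 0.282.

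**Figure D3:**
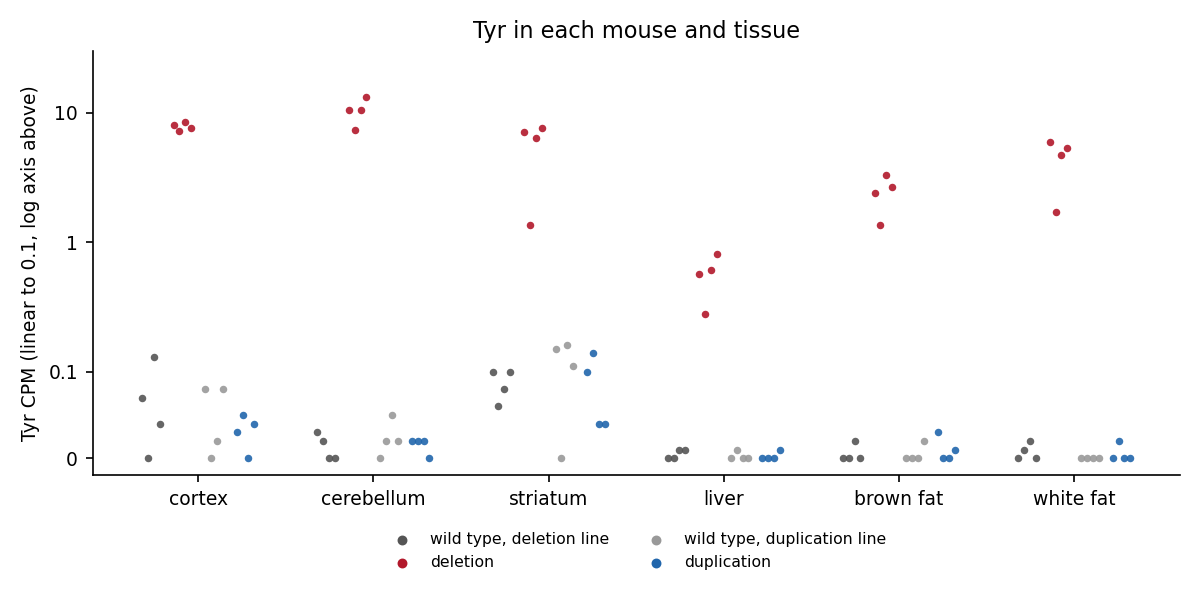
Tyr in CPM of each mouse (points) in each tissue by group, on an axis that is linear up to 0.1 and logarithmic above. The 4 deletion mice lie above the 12 others in each of the 6 tissues.

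In cortex of deletion mice, Kcnj2, which encodes the potassium channel Kir2.1 that sets resting potential, rose by 0.83 ± 0.14, from 18.8 ± 3.27 to 33.4 ± 5.74 CPM (adjusted p = 0.00468). The peptide gene Edn1 (endothelin 1) rose by 0.66 ± 0.17 (adjusted p = 0.0485). The clock gene Per1 fell by 0.89 ± 0.17, from 108 ± 7.89 to 58.5 ± 9.53 CPM (adjusted p = 0.0198). Dusp5, a phosphatase that acts on ERK, fell by 0.85 ± 0.20 (adjusted p = 0.0439), and Arl4d, a small GTPase, by 0.83 ± 0.17 (adjusted p = 0.0204). Of 20178 genes tested outside the interval, 265 were higher and 95 lower, against 523 and 296 with DESeq2. Protein-coding genes gave 90 of the rises and 90 of the falls, and processed pseudogenes, copies made from mRNA whose counts can hold reads of their parent genes, gave 158 rises and 2 falls among 1767 tested. The count of 360 was 147 without deletion 2, 159 without deletion 3, 204 without wild type 5, 214 without wild type 6 and 155 without wild type 7. Of the 180 protein-coding calls, 61 were kept with offsets for GC content and length, 125, 42, 39 and 92 without deletion 1, 2, 3 and 4, and 60, 82, 41 and 117 without wild type 5, 6, 7 and 8. Of the 160 pseudogene calls, 133, 94, 106 and 115, and 120, 101, 95 and 121, were kept without the same mice. Kcnj2 stayed past the threshold with any 1 mouse left out. Edn1 was lost without any mouse of the line except wild type 8 (adjusted p up to 0.147) and Dusp5 without any except deletion 4 (up to 0.153). Per1 and Arl4d were lost without deletion 2, deletion 3, wild type 5 or wild type 7 (up to 0.0813 and 0.0891).

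Fixed gene lists gave the same cortex a second view. The activity-induced immediate early genes were lower in deletion mice, with a median of -0.46 over 22 genes (camera adjusted p = 2.51e-08, and adjusted p = 0.551 with an estimated correlation). Of them 9 were lower when adjusted over the list alone, including Klf2 (-0.52 ± 0.14), Fosb (-0.47 ± 0.13), the kinase-inducible gene Ier5 (-0.40 ± 0.12) and the ERK phosphatase Dusp6 (-0.57 ± 0.17). Circadian clock genes had a median of -0.13 (adjusted p = 0.0186, and adjusted p = 0.736 with an estimated correlation), with Per1, the repressor Bhlhe40 (-0.64 ± 0.12, adjusted p = 0.00989), Per2 (-0.62 ± 0.15) and Tef (-0.22 ± 0.06) lower when adjusted over the list alone. Genes of dopamine signalling and striatal projection neurons were positive in 21 of 21, with a median of 0.41 (adjusted p = 2.51e-07, and adjusted p = 0.796 with an estimated correlation), and their transcription factor Foxp1 rose by 0.30 ± 0.08. Many of these genes mark striatal neurons, and whether the cortex libraries differed in the tissue they held was not tested. Their rise therefore does not show a change of signalling in cortex. Oligodendrocyte and myelin markers had a median of -0.10 (adjusted p = 0.00910, and adjusted p = 0.844 with an estimated correlation), with Mal (-0.29), the gap junction gene Gjb1 (-0.27) and Opalin (-0.31) among 5 lower genes when adjusted over the list alone. Single members also passed in lists whose test did not. Fezf2, which specifies deep-layer projection neurons, fell by 0.40 ± 0.08 (adjusted p = 0.0145), while the cortical excitatory layer markers had a median of 0.02, with 3 higher and 2 lower of 21 when adjusted over the list alone (camera adjusted p = 0.960, and adjusted p = 0.990 with an estimated correlation). Gad2, a GABA-synthesizing enzyme, rose by 0.23 ± 0.05 (adjusted p = 0.0295), while the GABA neuron markers had a median of 0.05, with 1 higher and 1 lower of 21 (camera adjusted p = 0.276, and adjusted p = 0.796 with an estimated correlation).

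In cortex of duplication mice, Jund, a member of the AP-1 transcription factors, rose by 0.46 ± 0.07, from 155 ± 19.9 to 213 ± 15.7 CPM (adjusted p = 0.00369). The linker histone gene H1fx rose by 1.01 ± 0.19 (adjusted p = 0.0418) and the transcription factor Gata2 by 0.53 ± 0.10 (adjusted p = 0.0312). The matrix protein gene Ccn1, induced by growth factors, fell by 1.74 ± 0.31, from 17.2 to 5.08 CPM (adjusted p = 0.0418). The endothelial early response gene Apold1 fell by 0.87 ± 0.18 (adjusted p = 0.0418), and Calb2, the calretinin of interneurons, by 0.53 ± 0.10 (adjusted p = 0.0348). A total of 38 genes were higher and 3 lower outside the interval (100 and 33 with DESeq2), of which 15 rises and 3 falls were protein-coding and 23 rises were processed pseudogenes. The count of 41 was 17, 16, 8 and 15 without duplication 1, 2, 3 and 4, and 13, 17, 18 and 14 without wild type 1, 2, 3 and 4. Jund stayed past the threshold with any 1 mouse left out, and H1fx was lost without any of the 8 mice of the line (adjusted p up to 0.176). Ccn1 was lost without any mouse of the line except duplication 4 (up to 0.165). Gata2 was lost without duplication 1, 2 or 3 or wild type 2, 3 or 4 (up to 0.151), Apold1 without duplication 2, 3 or 4 or wild type 1, 2 or 4 (up to 0.165), and Calb2 without duplication 2, 3 or 4 or wild type 1 or 4 (up to 0.146). GABA neuron markers had a median of -0.10 (camera adjusted p = 0.00332, and adjusted p = 0.0768 with an estimated correlation), with Calb2 and Reln, a guidance protein of interneurons (-0.22 ± 0.06), lower when adjusted over the list alone. Camera also called oligodendrocyte and myelin markers (median 0.09, adjusted p = 0.00129) and blood cell transcripts (0.46, adjusted p = 0.0468) as higher. It called heat shock and unfolded protein response genes (-0.09, adjusted p = 0.001), chromatin regulators linked to autism (-0.06, adjusted p = 0.00143) and interferon response genes (-0.13, adjusted p = 0.00927) as lower. With an estimated correlation the adjusted p of these 5 lists was 0.790, 0.777, 0.682, 0.785 and 0.834.

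Immediate early genes were lower in all 3 brain tissues of duplication mice than in their wild types. Fos, an AP-1 factor induced by neuronal firing, went from 32.6 ± 3.14 to 14.3 ± 4.82 CPM in cortex, from 28.1 ± 8.35 to 7.83 ± 4.70 in cerebellum and from 19.0 ± 3.02 to 4.65 ± 2.66 in striatum, with adjusted p-values of 0.290, 0.999 and 1.00 over all genes and 0.0156, 0.0323 and 0.0152 when adjusted over the list alone. In cortex Btg2, an antiproliferative gene, fell by 1.32 ± 0.29, Ier2 by 1.07 ± 0.25, Fosb by 0.60 ± 0.13 and Klf2 by 0.47 ± 0.13. In cerebellum the orphan receptors Nr4a1 and Nr4a2 fell by 1.06 ± 0.24 and 1.15 ± 0.31, Fosb by 1.06 ± 0.26 and the neuronal factor Npas4 by 1.28 ± 0.39. In striatum Btg2 fell by 1.47 ± 0.28, Junb by 1.24 ± 0.29, the phosphatase gene Dusp1 by 0.95 ± 0.25 and Egr4 by 0.83 ± 0.22. Adjusted over the list alone, 9 of 22 genes were lower in cortex, 8 of 21 in cerebellum and 8 of 22 in striatum. The list had medians of -0.54, -0.54 and -0.62, with camera adjusted p-values of 4.16e-17, 1.54e-12 and 2.26e-32. The striatal call held (adjusted p = 0.00322 with an estimated correlation), while those of cortex (adjusted p = 0.0955 with an estimated correlation) and cerebellum (adjusted p = 0.0691 with an estimated correlation) were lost. With fry all 3 calls were kept (adjusted p = 0.0257 in cortex, 0.0477 in cerebellum and 0.0193 in striatum). The wild types of the duplication line lay above those of the deletion line, by medians of 0.59, 0.24 and 0.71 in cortex, cerebellum and striatum. In deletion mice the list was also lower than in their own wild types, by medians of -0.46 in cortex (above), -0.27 in cerebellum (camera adjusted p = 0.00198, and adjusted p = 0.736 with an estimated correlation) and -0.06 in striatum (camera adjusted p = 0.0239, and adjusted p = 0.8 with an estimated correlation). These calls were lost with fry (adjusted p = 0.136 in cortex, 0.486 in cerebellum and 0.768 in striatum).

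**Figure D4:**
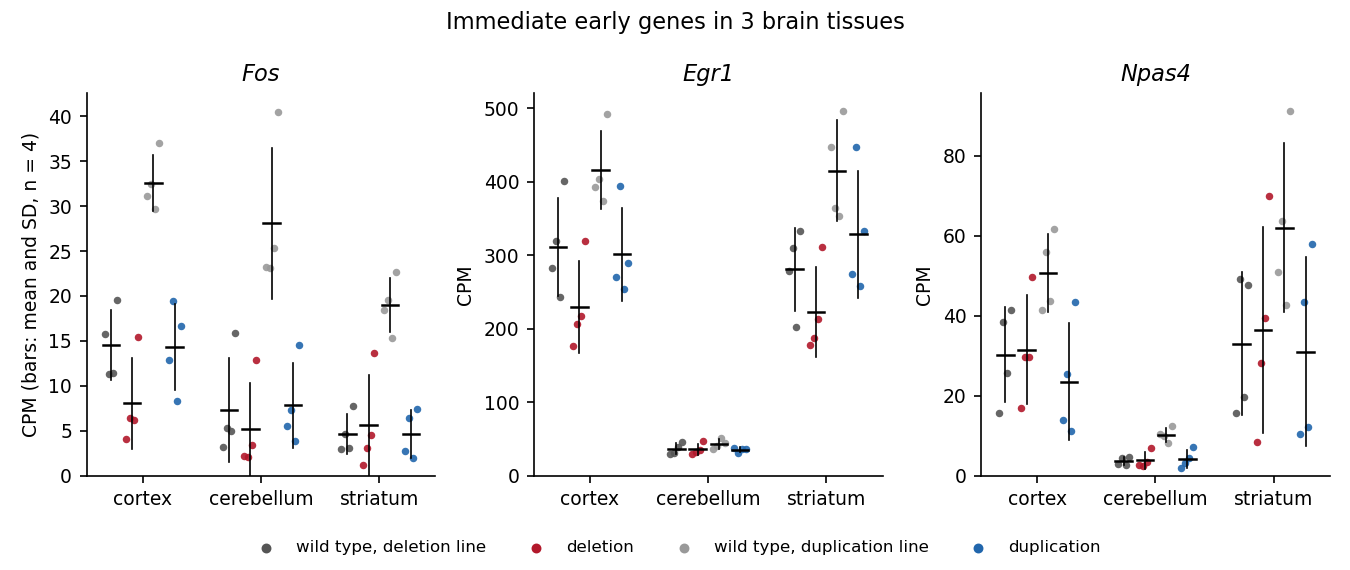
Levels in CPM of Fos, Egr1 and Npas4 in the brain tissues by group, with points for mice and bars for mean and SD (n = 4). Fos in cortex stands at 32.6 in wild types and 14.3 in duplication mice of the same line.

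In cortex 19 genes outside the interval were called in both lines. Fas and Spns2 moved in the direction of dosage, and all the others rose in both lines. Fas, the death receptor, fell by 0.83 ± 0.19 in deletion mice and rose by 1.06 ± 0.19 in duplication mice, and Spns2, a transporter of sphingosine 1-phosphate, fell by 0.34 ± 0.06 and rose by 0.28 ± 0.06. The actin-binding gene Marcks rose in both, by 0.31 ± 0.06 and 0.30 ± 0.06, and so did Gm20594, by 2.28 ± 0.17 and 1.18 ± 0.17. The other 15 of these 19 genes were processed pseudogenes higher in both lines, led by Gm11512 (3.33 to 10.5 CPM in the deletion line and 2.89 to 6.03 in the duplication line). Independent lists would share 2.06, but these lists are not independent. Both come from 1 fit with a shared dispersion estimate, and similar copies can share reads, so the overlap cannot be judged by that number. Of the 23 pseudogenes called in duplication mice, the number kept was 8, 10, 4 and 8 without duplication 1, 2, 3 and 4, 4, 10, 8 and 5 without wild type 1, 2, 3 and 4, 3 with pooled wild types and 3 with a replicate block. In duplication mice, 1 left-out mouse took the adjusted p to 0.0748 at most for the pseudogenes Gm6317 and Gm7150 and to 0.138 for Gm4960. Across genes outside the interval, which are not independent replicates, the effects in the 2 lines had a Pearson correlation of 0.119 in cortex, 0.173 in cerebellum, 0.07 in striatum, -0.438 in liver, 0.069 in brown fat and 0.451 in white fat. In cerebellum, striatum and brown fat its sign changed with 1 mouse left out (ranges below), so no direction can be read there. In cortex the correlation was 0.547 among processed pseudogenes and -0.069 among protein-coding genes.

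The reciprocal contrast asked which genes the duplication and the deletion moved apart, and uses all 16 mice. Outside the interval, the smallest p in cortex was that of Spns2 (0.62 ± 0.08, adjusted p = 0.000404), followed by Tyr, Fas (1.88 ± 0.27, adjusted p = 0.00143) and Cdh15, an adhesion molecule of muscle and cerebellum (2.63 ± 0.38, adjusted p = 0.00143), which fell by 2.56 in deletion mice and moved by 0.07 in duplication mice. Kcnj2 (-0.99 ± 0.19, adjusted p = 0.0375), Gata2 (0.86, adjusted p = 0.00714), the glucocorticoid-induced factor Klf15 (0.80, adjusted p = 0.0116) and Neurod2, a factor of cortical neurons (0.38, adjusted p = 0.0305), also passed. Outside the interval, 37 genes were higher and 19 lower, against 291 and 293 with DESeq2. The count of 56 was 208 without deletion 1, 115 without wild type 1, 31 without duplication 4, 27 without deletion 3, 26 without deletion 2 or duplication 2, 24 without duplication 3 or wild type 7, and 20 without wild type 2. These genes outside the naming rule were chosen after their values were seen.

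In cerebellum of deletion mice, Gdf11, a secreted factor that limits neuron number, fell by 0.60 ± 0.09, from 22.0 to 14.6 CPM (adjusted p = 0.00928), and Tyr was the other of the 2 genes called. Gdf11 was lost without deletion 1, deletion 3 or deletion 4 (adjusted p up to 0.0654), which left a count of 1, and the count was 3 without wild type 6 or wild type 7. In striatum, Aldoart1, a retrocopy of Aldoa on chromosome 4 whose counts can hold reads of Aldoa, fell by 1.25 ± 0.16, from 6.83 to 2.90 CPM (adjusted p = 0.00243), again beside Tyr. Choroid plexus and ependyma markers were positive in 17 of 17 in striatum of deletion mice (median 1.77, camera adjusted p = 1.07e-15, and adjusted p = 0.495 with an estimated correlation). Their most abundant gene Ttr, the thyroxine carrier, ranged from 282 to 4988 CPM in deletion mice and from 18.8 to 1615 in their wild types. It stood at 3031, 4988, 1901 and 282 CPM in deletion 1 to 4. The library of deletion 2 also held the cerebellar gene Gabra6 at 34.7 and Alb at 82.8 CPM. In duplication mice edgeR called 0 genes outside the interval in both tissues, with 595 in cerebellum and 258 in striatum at an unadjusted p under 0.05, and DESeq2 called 2 higher and 7 lower in cerebellum and 2 lower in striatum. The reciprocal contrast called the same 2 genes as the deletion in each tissue, with Gdf11 at 0.98 ± 0.12 and Aldoart1 at 1.69 ± 0.22. Its cerebellar count was 1 without wild type 3 and 3 without wild type 5. Its striatal count was 1 without duplication 1, 3 or 4 or wild type 1, 3, 4, 6, 7 or 8, 3 without duplication 2 and 4 without deletion 2.

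In liver of deletion mice, Sdr9c7, a short-chain dehydrogenase, fell by 1.25 ± 0.17, from 9.91 ± 4.47 to 4.05 ± 2.03 CPM (adjusted p = 0.00674). Its wild types differed by sex, with 12.5 and 14.9 CPM in males and 5.96 and 6.30 in females. Deletion 1, a male, stood at 7.05 CPM, above both wild-type females. Slc25a32, a mitochondrial carrier of folate, fell by 1.14 ± 0.16, from 8.49 ± 1.87 to 3.85 ± 0.862 CPM (adjusted p = 0.00853). The guidance receptor Robo1 fell by 2.05 ± 0.30, from 3.44 ± 2.14 to 0.752 ± 0.343 CPM (adjusted p = 0.0133). Its wild types also differed by sex, with 1.43 and 1.77 CPM in males and 5.18 and 5.40 in females. Lmna, the lamin of the nuclear envelope, rose by 0.67 ± 0.12, from 12.5 to 19.9 CPM (adjusted p = 0.0458). In all 3 genes were higher and 6 lower outside the interval, and DESeq2 called 421 and 459. The count of 9 was 30 without deletion 2, 6 without deletion 3, 5 without wild type 5 and 4 without wild type 6, 7 or 8. Sdr9c7 and Slc25a32 stayed past the threshold with any 1 mouse left out, Lmna was lost without any mouse of the line except deletion 1 and deletion 2 (adjusted p up to 0.142), and Robo1 without deletion 3, deletion 4 or wild type 6, 7 or 8 (up to 0.0621). Among lipogenesis genes, Acaca (-0.56 ± 0.15), Scd1 (-1.22 ± 0.35), Scd2, Lpin1 and Pklr were lower and Agpat2 (0.42 ± 0.14) higher when adjusted over the list alone, and the list as a whole missed the threshold (camera adjusted p = 0.0514). The fasting hormone gene Fgf21 fell by 2.87 ± 0.72 and the glucose 6-phosphatase gene G6pc by 0.95 ± 0.25, each past the threshold when adjusted over its list alone.

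In liver of duplication mice edgeR called 0 genes outside the interval, with 649 at an unadjusted p under 0.05, and DESeq2 called 9 higher and 10 lower. Endothelial and vascular markers were negative in 19 of 19, with a median of -0.23 (camera adjusted p = 6.59e-08, and adjusted p = 0.0900 with an estimated correlation). Skeletal muscle markers were negative in 20 of 20 too, with a median of -2.54 (camera adjusted p = 0.00220, and adjusted p = 0.939 with an estimated correlation), and the muscle actin Acta1 stood at 154 and 84.9 CPM in liver of wild types 2 and 4, 47.2 in duplication 1 and 1.41 or less in the other 5 mice of the line. The heat shock genes Hspa1a (-1.71 ± 0.45) and Hspa1b (-1.63 ± 0.41) and the clock outputs Dbp (-3.01 ± 0.90) and Bhlhe41 (-3.12 ± 0.73) fell past the threshold when adjusted over the list alone. The reciprocal contrast called 6 genes higher and 1 lower in liver, among them the collagen gene Col27a1 (1.93 ± 0.29, adjusted p = 0.0117), the metalloproteinase Mmp14 (-1.14 ± 0.17, adjusted p = 0.0117) and Angptl4, an inhibitor of lipoprotein lipase (2.71 ± 0.48, adjusted p = 0.0482), chosen after their values were seen. The count of 7 was 22 without deletion 2, 13 without duplication 1, 4 without deletion 3, duplication 2 or duplication 3, and 3 without wild type 1.

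In brown fat, skeletal muscle markers were positive in 20 of 20 in deletion mice, with a median of 4.55 (camera adjusted p = 9.03e-18, and adjusted p = 0.551 with an estimated correlation). Acta1, the actin of muscle, ranged from 1.75 to 1390 CPM in their wild types and from 130 to 13316 in deletion mice. Ucp1, the uncoupling protein of brown adipocytes, stood at 0.39 CPM in the library labelled brown fat of wild type 1 and at 11025 in the library labelled white fat of the same mouse. Outside the interval edgeR called only Tyr in deletion mice, with 752 genes at an unadjusted p under 0.05, and DESeq2 called 2 higher. It called 0 in duplication mice, with 1012 genes at an unadjusted p under 0.05, and DESeq2 called 3 higher and 34 lower. The count of 1 in deletion mice was 0 without any mouse of the line except deletion 2. In the reciprocal contrast edgeR called 0, with 1232 at an unadjusted p under 0.05, and DESeq2 called 2 higher and 14 lower.

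In white fat, white adipocyte genes were positive in 25 of 25 in duplication mice, with a median of 2.10 (camera adjusted p = 5.03e-14, and adjusted p = 0.389 with an estimated correlation). Adjusted over the list alone, 7 were higher, among them Car3 (2.96), the lipid droplet gene Plin4 (2.68) and the adipokine Retn (3.28). Macrophage markers (median 1.64, camera adjusted p = 2.17e-09, and adjusted p = 0.398 with an estimated correlation) included Adgre1 (1.41), and extracellular matrix genes (median 1.39, camera adjusted p = 9.46e-11, and adjusted p = 0.472 with an estimated correlation) rose as well. Among the wild types, wild type 1 held Ucp1 at 11025 CPM, and wild types 3 and 4 held the epididymal gene Lcn5 at 5665 and 6036 CPM. Adipoq stood at 490, 198, 67.7 and 89.7 CPM in wild types 1 to 4 and 831, 1205, 119 and 1883 in duplication 1 to 4. The rises of these lists cannot be told apart from such differences in the tissue the libraries held. White fat of duplication 1 held liver transcripts (Alb at 91647 and Apoa1 at 1671 CPM), so the rises of the retinol carrier Rbp4 (3.57) and of fibronectin, Fn1 (2.82), which liver also makes, can come in part from that library. In deletion mice interferon response genes had a median of 0.92 (camera adjusted p = 3.18e-08, and adjusted p = 0.522 with an estimated correlation), with Rsad2 (2.20 ± 0.40) and Ifit3 (1.63 ± 0.39) higher when adjusted over the list alone. Adipoq stood at 70.8, 166, 1409 and 1511 CPM in wild types 5 to 8 and 1197, 1143, 1556 and 1717 in deletion 1 to 4. Wild types 5 and 6 also held Lcn5 (below). The interferon rise cannot be told apart from such differences in tissue either. Epididymis markers were lower in both comparisons, by medians of -5.95 and -5.05 (camera adjusted p = 5.04e-07 and 1.03e-05, and adjusted p = 0.311 and 0.551 with an estimated correlation). The epididymal lipocalin Lcn5 stood at 3044 to 7798 CPM in white fat of wild types 3 to 6 and duplication 3, and at 37.8 or less in the other 11 libraries. Outside the interval edgeR called 0 genes in either line, with 2595 and 2817 at an unadjusted p under 0.05 in deletion and duplication mice, while DESeq2 called 69 higher and 267 lower, and 778 higher and 436 lower. Without wild type 1 the duplication count was 1. The reciprocal contrast called 0 genes with edgeR (1065 at an unadjusted p under 0.05, and 28 higher and 10 lower with DESeq2), 38 without duplication 1 and 10 without duplication 4.

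**Figure D5:**
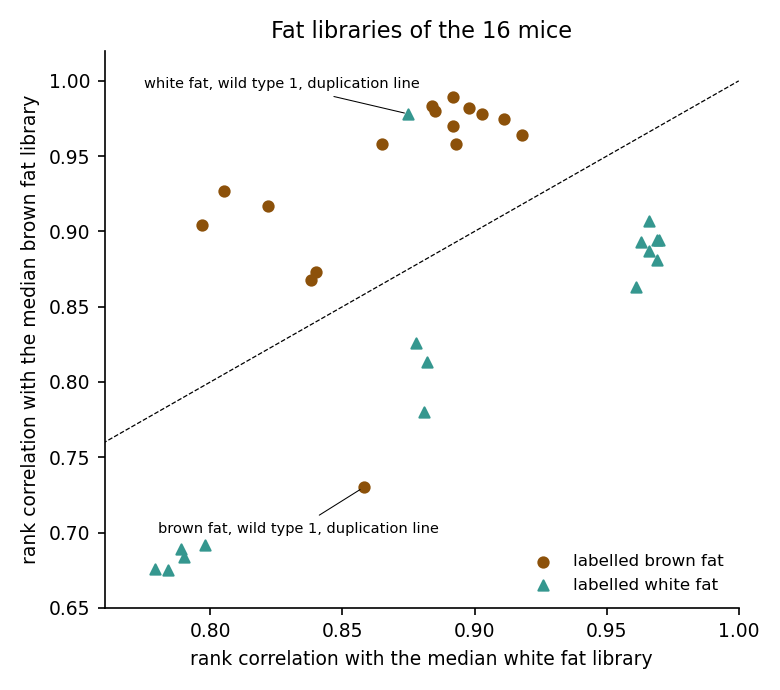
Rank correlation of each fat library with the median brown fat library and the median white fat library, with a line where both are equal. The library labelled brown fat of wild type 1 (0.73 and 0.858) and the library labelled white fat of the same mouse (0.978 and 0.875) lie on the side of the other tissue.

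The average over the 6 tissues asked which genes changed in the whole animal. In deletion mice, Tyr (6.26 ± 0.25, adjusted p = 1.06e-08) was called outside the interval, along with 19 of 34 interval genes, led by Tbc1d10b, an activator of Rab GTPases (-0.97 ± 0.06, adjusted p = 3.31e-06), Taok2 (-1.02 ± 0.08) and Kctd13 (-1.13 ± 0.09). In duplication mice the interval genes Taok2 (0.68 ± 0.08), Tbc1d10b (0.59 ± 0.06), Cd2bp2 (0.59 ± 0.08) and Maz (0.59 ± 0.09) passed. Limma called 0 genes outside the interval there, with 749 at an unadjusted p under 0.05 and no other tool run. The interval count of 4 was 3 without wild type 1 and 2 without wild type 3, wild type 4 or any duplication mouse. The reciprocal contrast called Tyr and 24 interval genes, and its count outside the interval was 3 without deletion 1 or deletion 2 and 2 without wild type 2. The deletion count outside was 3 without wild type 7. Called in the same direction in at least 2 tissues outside the interval were Tyr in deletion mice and, with edgeR, 0 genes in duplication mice, also 0 at an adjusted p under 0.1.

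The wild types of the 2 lines were compared as a measure of what line, litter label and age contribute. In cortex Fbxo33, a ubiquitin ligase subunit, was higher in the duplication line by 0.38 ± 0.06 (adjusted p = 0.0399), the only gene called of 20178, while 2303 had an unadjusted p under 0.05 and DESeq2 called 116 higher and 100 lower. In liver Tmc7, a channel-like membrane protein, was lower by -2.65 ± 0.35 (adjusted p = 0.0377), and it fell by 2.55 ± 0.35 in deletion mice against their own wild types. In the other 4 tissues edgeR called 0 genes, with 525 in cerebellum, 679 in striatum, 3849 in brown fat and 1199 in white fat at an unadjusted p under 0.05, and DESeq2 called 6 higher and 2 lower, 7 and 2, 984 and 148, and 27 and 16. In brown fat, Ucp1 stood at 0.39, 303, 7449 and 3202 CPM in wild types 1 to 4 and at 3424 to 4921 in wild types 5 to 8. The brown fat counts can thus hold a difference in the tissue sampled, and do not measure line, litter label and age alone. The cortex count of 1 was 0 without wild type 2, 4, 5, 6 or 7, 4 without wild type 1 and 5 without wild type 3, and the liver count of 1 was 0 without wild type 5, wild type 7 or any of wild types 1 to 4. Fbxo33 and Tmc7 were chosen after their values were seen.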

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

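Chosen only after the result was seen were the tests on the genes around Tyr, on a Tyr copy carried with the engineered chromosome, on GC content and length, on the pseudogenes in other tissues, on the wild types of the 2 lines for immediate early genes, and on splits counted at an unadjusted p. Chance alone sets a sample apart in about 1 in 20 groups, and here a sample stood apart in 14 of 120 groups of library measures and in 12 of 158 groups of gene levels.

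Tyr, the enzyme that starts melanin synthesis, was transcribed in deletion mice in tissues that hold few pigment cells. Cells that make pigment are argued against in part, since 9 markers of such cells, among them Dct, Pmel and Sox10, had a median log2 fold change of 0.26. In cortex, where Tyr rose by 6.81 ± 0.39, Dct stood at -0.06 ± 0.33 and Pmel at 0.43 ± 0.23. Other values had a wide SE and cannot decide. Among them were Tyrp1 in cerebellum (0.77 ± 0.65), Mlana in brown fat (0.81 ± 1.32) and Dct in white fat (2.2 ± 0.86). Of their 31 gene and tissue pairs, 0 passed edgeR's threshold. Extra copies of the chromosome around Tyr are argued against less firmly, since 7 genes within 1 Mb had a median of 0.1, many with a wide SE. In cortex Grm5 stood at -0.1 ± 0.08, but Ctsc at 0.31 ± 0.12. That 0 of these 26 pairs and 0 of the 31 marker pairs passed the threshold says little. Simulated 1.5-fold changes were recovered in 16.2% of genes in striatum and in fewer in every other tissue but cortex. A Tyr copy carried with the engineered chromosome stays open, since vectors for chromosome engineering can carry a tyrosinase minigene as a coat colour marker. All deletion mice lay above all other mice in 6 of 6 tissues, as such a copy would give, but carrying it and carrying the deletion cannot be told apart here.

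In cortex of deletion mice 158 processed pseudogenes were higher, among them Gm11512 (1.66 ± 0.09) and Gm6977 (1.36 ± 0.12), although the share of all processed pseudogenes in the counts was not higher (5.64 to 6.04% against 5.5 to 6.56% in wild types) and that of mitochondrial genes was 8.8 to 9.7% against 7.3 to 9.0%. A bias of GC content or length is argued against, since 96.2% kept the call with offsets for both and their median log2 fold change went from 1.29 to 1.31 (median SE 0.22). Reads of abundant parent genes placed at these copies stay open, since over pseudogenes the effect had a Spearman correlation of 0.13 with the parent's CPM and of -0.49 with the identity to the parent. A genotype effect in every tissue stays open as well: the median was under 0.2 in 1 tissue, cerebellum (-0.11), where libraries stand apart, and was 0.29 in striatum, 0.44 in liver, 0.45 in brown fat and 0.30 in white fat. Libraries stand apart there too. Processed pseudogenes took 10.23, 12.03 and 10.13% of counts in striatum, brown fat and white fat of deletion 2. Wild types of the line reached 7.22, 7.15 and 8.44%. Whether those medians rest on deletion 2 was not tested. In duplication mice the same genes had medians of 0.56 in cortex and of -0.17, -0.08, -0.01, -0.1 and -0.28 in cerebellum, striatum, liver, brown fat and white fat.

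Fos, Junb, Btg2, Dusp1 and other immediate early genes, which neurons switch on within minutes of firing, were lower in brains of duplication mice than in their wild types. An effect of the duplication seen against any wild type stays open: against all 8 wild types the medians of the list were -0.29 in cortex, -0.35 in cerebellum and -0.41 in striatum, but these hold the same 4 wild types that showed the fall and add no independent support. Against the wild types of the deletion line the medians were 0.08, -0.02 and 0.14, which was the wrong bound to exclude it by, since that comparison also crosses line, litter label and age. A difference between the 2 sets of wild types stays open too, since those of the duplication line lay above those of the deletion line by at least a median of 0.24. With line, litter label and age going together in the wild types, these explanations cannot be told apart.

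Other splits of the 8 mice of a line tested whether chance can be excluded, with 35 splits in each case and carriers left in place for the wild types of the 2 lines. For the reciprocal contrast they were random regroupings of both lines, not all possible ones, and some can keep the true groups of 1 line. Chance is called excluded where only the true grouping was as large, 1 of 35, the lowest share possible. The number of tests was not adjusted for, so some can rank first by chance. In cortex chance was excluded for the deletion (360 genes outside the interval, at most 1 in another split, 1 of 35 as large), the duplication (41, at most 2, 1 of 35) and the reciprocal contrast (56, at most 24, 1 of 35), but not for the wild types (1, at most 1, 2 of 35). For interval genes it was excluded in cortex of both lines (30 and 23 genes, at most 0, 1 of 35 each), in cerebellum of both lines (16 and 2, at most 0, 1 of 35 each), and in striatum and liver of deletion mice (15 and 8, at most 0, 1 of 35 each). Outside the interval it was excluded for the deletion in cerebellum (2, at most 1, 1 of 35), liver (9, at most 1, 1 of 35) and brown fat (1, at most 0, 1 of 35), and for the reciprocal contrast in cerebellum (2, at most 0, 1 of 35). It was not excluded for the deletion in striatum (2, at most 6, 3 of 35), the reciprocal contrast in striatum (2, at most 4121, 3 of 35) and liver (7, at most 1577, 2 of 35), and the wild types in liver (1, at most 1, 2 of 35). The counts of 1 and 2 that excluded chance are Tyr, alone in brown fat and with Gdf11 in cerebellum, and say nothing of other genes.

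The number of genes at an unadjusted p under 0.05 did not always go the same way. It did not exclude chance for the deletion in cortex (3165 genes, at most 3301 in another split, 2 of 35 as large), cerebellum (499, at most 6464, 20 of 35) and brown fat (752, at most 3237, 7 of 35), or for the reciprocal contrast in cerebellum (445, at most 4602, 16 of 35). It excluded chance for the duplication (1915, at most 1873, 1 of 35) and the reciprocal contrast (2933, at most 2063, 1 of 35) in cortex, for the deletion in liver (3789, at most 2452, 1 of 35) and white fat (2595, at most 1889, 1 of 35), and for the wild types in liver (1090, at most 973, 1 of 35) and brown fat (3849, at most 3327, 1 of 35). In brown fat the library of wild type 1 lay nearer to white fat (0.73 with brown and 0.858 with white fat). That count need not come from line, litter label or age.

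Every count of 0 was met by all 35 splits. For genes outside the interval in duplication mice the highest other split called 68 in cerebellum, 92 in striatum, 3 in liver, 1808 in brown fat and 2066 in white fat, against 0 for the true groups. For the reciprocal contrast it called 1 in brown fat and 41 in white fat, for the deletion 0 in white fat, and for the wild types 2098 in cerebellum, 0 in striatum, 0 in brown fat and 7 in white fat. For interval genes with a count of 0 the highest was 0 in striatum and liver of duplication mice, 0 in both fats of deletion mice, and 2 in brown and 5 in white fat of duplication mice. Splits that call so many genes point to a structure of the samples, whose source was not tested.

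For the correlation between lines, its size was reached by 2 (mice of the deletion line split) and 3 (mice of the duplication line split) of 35 splits in cortex (0.119, highest other 0.14 and 0.126), 20 and 11 in cerebellum (0.173, 0.368 and 0.255), 15 and 26 in striatum (0.07, 0.17 and 0.453), 12 and 13 in liver (0.438 in size, 0.488 and 0.619), and 31 and 30 in brown fat (0.069, 0.649 and 0.589). In white fat it was reached by 1 and 3 (0.451, 0.444 and 0.724). The true groups thus ranked first only in white fat, and there only for splits of the deletion line, by 0.451 to 0.444. Among so many tests such a rank can arise by chance. For the average over tissues, 2 of 35 splits were as large for the deletion (1 gene, at most 2), 35 for the duplication (0, at most 48), 5 for the reciprocal contrast (1, at most 1) and 35 for the wild types (0, at most 0). The split refits of the test between tissues, run on interval genes and drawn genes, called 0 in deletion mice in place of 2 (at most 2 in other splits) and 0 in duplication mice (at most 12), so all 35 were as large. Genes called in at least 2 tissues were as many in 2 of 35 splits for the deletion (1, at most 1) and 35 for the duplication (0, at most 64), and in at least 3 tissues in 1 for the deletion (1, Tyr, at most 0, chance excluded) and 35 for the duplication (0, at most 1). Lists called by camera other than the interval were as many in 22 of 35 splits for the deletion (50, at most 70) and 27 for the duplication (48 in the refits, at most 70), so chance was not excluded.

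Libraries far from the others of their group came first from deletion 2 and wild type 5. In striatum deletion 2 had 10.28% spike-ins (rest 1.16 to 1.61), 7.2% mitochondrial counts (rest 9.5), 10.23% processed pseudogene counts (rest 5.78 to 6.31) and a rank correlation with other libraries of 0.929 (rest 0.99 to 0.992). Its correlation was 0.941 in liver (rest 0.974 to 0.975) and 0.965 in cerebellum (rest 0.989 to 0.991), where pseudogenes took 7.98% (rest 5.37 to 5.7). Wild type 5 in cerebellum had a correlation of 0.946 (rest 0.99 to 0.992) and 8.44% pseudogene counts (rest 5.68 to 5.81). The others were the library labelled white fat of wild type 1, with 25.6% mitochondrial counts (rest 4.0 to 4.7), as brown fat has, duplication 1 in cortex with 9.9% mitochondrial counts (rest 7.4 to 7.6), deletion 3 in cortex with a correlation of 0.992 (rest 0.993), duplication 2 in striatum with 5.21% pseudogene counts (rest 6.25 to 6.39) and wild type 7 in brown fat with 0.34% spike-ins (rest 0.28 to 0.29).

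Single genes set a mouse apart in CPM as follows. In the libraries just named, Asphd1 stood at 55.1 in cerebellum of wild type 5 (rest 19.1 to 21.7), at 20.7 in cerebellum of deletion 2 (rest 9.25 to 10.8) and at 26.1 in its striatum (rest 10.8 to 12.1), Taok2 at 97.8 in cerebellum of wild type 5 (rest 145 to 154) and Pagr1a at 4.16 in liver of deletion 2 (rest 2.27 to 2.59). In cortex of wild type 7, Kctd13 stood at 77.2 (rest 68.5 to 69.6), Sez6l2 at 404 (rest 368 to 369) and Gdpd3 at 3.06 (rest 0.157 to 0.332). Maz stood at 172 in cerebellum of wild type 2 (rest 131 to 137), Fos at 40.5 in cerebellum of wild type 4 (rest 23.2 to 25.4), Gdf11 at 23.2 in cerebellum of wild type 6 (rest 21.6 to 21.7), and Tyr at 0.0165 in brown fat of wild type 7 (rest 0).

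Between tissues, a test of the deletion effect passed for Pagr1a and Asphd1 (adjusted p = 0.0482 each), but that of Asphd1 includes 3 tissues where it was too low to be measured, its effects in the brain tissues being alike, and the counts of Pagr1a can hold reads of Prrt2, a brain gene. Without the libraries of unusual rank correlation, shares or markers their adjusted p was 0.370 and 0.574, but 0 genes were called without deletion 1 or any of wild types 6 to 8 either, so the loss does not single out those libraries. In other genes every carrier lay above the wild-type mean in 1 tissue and below it in another, a difference that was not tested. In deletion mice these were Vav3 (0.5 in cortex, -0.5 in white fat), Gdf11 (0.73 in white fat, -0.6 in cerebellum), Lmna (0.67 in white fat, -0.12 in cortex), Robo1 (0.17 in cortex, -2.05 in liver), and the pseudogenes Gm6977 (1.36 in cortex, -0.69 in cerebellum) and Gm11658 (1.25 in cortex, -0.19 in striatum). In duplication mice they were H1fx (1.01 in cortex, -1.28 in brown fat), Gata2 (0.53 and -1.69), Jund (0.46 and -0.71), Gm20594 (1.18 in cortex, -1.17 in white fat), Arc (0.28 in cerebellum, -1.46 in white fat), and the pseudogenes Gm11512 (1.06 in cortex, -0.01 in white fat), Gm7150 (1.15 in cortex, -0.45 in cerebellum), Gm9034 (0.88 in brown fat, -0.45 in white fat), Gm11198 (1.01 in cortex, -0.36 in cerebellum) and Gm11658 (1.0 in brown fat, -0.34 in cerebellum). In 9 of 96 libraries the spike-ins, which the comparisons do not use, lay nearer to the other mix than to the one on the label. These were deletion 4 in cerebellum, wild types 3 and 4 and duplication 1 and 2 in liver, and the same 4 mice in white fat.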

How the results depend on the processing

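Chosen only after the data were seen were the fits without libraries that stood apart, without white fat libraries holding epididymis transcripts, with offsets for GC content and length, with protein-coding genes or processed pseudogenes alone, and, for the wild types of the 2 lines, the correlation between lines and the test between tissues, some of the scalings and left-out mice. The fall of Prrt2, Kctd13, Mapk3, Taok2 and Aldoa in cortex of deletion mice passed the threshold under all 19 alternatives run for each, and so did the rises of Tyr and Gm20594 there. In cortex of duplication mice, Prrt2, Kctd13, Taok2, Sez6l2, Maz and Asphd1 passed under all 20, Aldoa under 19, and Mapk3 passed under 5. Kcnj2 passed under 17 of 19 (log2 fold change 0.58 to 1.09) and Jund under 18 of 20 (0.25 to 0.55). Of the comparisons of single genes and lists with an alternative, 1333 were counted as the same, 241 lost the threshold, 33 passed it and 0 of the called ones changed sign. The 1333 can include changes of sign where neither fit passed, and comparisons without an adjusted p. Of the comparisons of counts and correlations, 694 were the same and 300 moved. A count moved if it changed by over 1.5-fold, and a correlation if it changed by over its SD with single mice left out. Of the 360 genes called in cortex of deletion mice, DESeq2 kept 354, RLE size factors 355 and the fit with GC and length offsets 228, which kept 154 of 160 pseudogenes and 61 of 180 protein-coding genes. Of the 41 in duplication mice these fits kept 40, 40 and 28. Except where the setting itself tests fewer mice or genes, the cause of each difference below was not tested. Simulated 2-fold changes were recovered in 1% of genes in brown fat and 0% in white fat, so a count of 0 there says little, and whether depth or the spread between mice limits it was not tested.

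The counts below are of genes outside the interval unless the interval is named. DESeq2 gave, in cortex, cerebellum, striatum, liver, brown fat and white fat, 819, 14, 9, 880, 2 and 336 for the deletion, 133, 9, 2, 19, 37 and 1214 for the duplication, 584, 15, 9, 233, 16 and 38 for the reciprocal contrast, and 216, 8, 9, 68, 1132 and 43 for the wild types of the 2 lines. It called 16, 7 and 9 interval genes in liver, brown fat and white fat of deletion mice, and 13, 7, 10 and 7 in cerebellum, striatum, liver and white fat of duplication mice. With RLE size factors, 5 interval genes were called in liver of deletion mice and 1 in duplication mice, and the liver split of 3 higher and 6 lower genes became 1 and 6. With GC and length offsets, the deletion count was 4 in cerebellum, 17 in liver and 1 in white fat, the reciprocal count 22 in cortex, 4 in cerebellum and 14 in liver, and the wild-type count 0 in liver. Interval genes called were then 15, 1 and 1 in liver, brown fat and white fat of deletion mice and 10, 12 and 4 in cerebellum, striatum and liver of duplication mice, and the cortex correlation between lines was 0.15.

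With the 8 libraries of 1 line alone, the deletion count was 167 in cortex, 1 in cerebellum, 0 in striatum and 1 in liver, and the duplication count 26 in cortex and 1 in white fat. Interval genes called were 0, 3 and 1 in cerebellum, striatum and liver of deletion mice and 6 and 1 in cerebellum and striatum of duplication mice. With all 8 wild types as controls, the deletion count was 4 in cerebellum, 24 in liver and 1 in white fat, the duplication count 16 in cortex, and the reciprocal count 167, 5, 27, 1 and 1 in cortex, cerebellum, liver, brown fat and white fat. Interval genes called were 13 in liver of deletion mice and 7, 7 and 3 in cerebellum, striatum and liver of duplication mice. Without a low-count filter, the deletion count was 1 in cerebellum and 1 in white fat, the reciprocal count 101 in cortex and the wild-type count 4 in cortex. Without the sex term, the liver counts were 4 for the deletion, 1 for the reciprocal contrast and 0 for the wild types, the wild-type count in cortex was 2, and interval genes called were 5 in liver of deletion mice and 4 and 1 in cerebellum and liver of duplication mice. With protein-coding genes only, the cortex counts were 101, 16 and 3 for the deletion, the duplication and the wild types, and interval genes called were 5 in liver of deletion mice and 4 and 1 in cerebellum and liver of duplication mice. The cortex correlation was -0.069 over these genes.

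In females only, the deletion count was 59 in cortex, 1 in cerebellum and 0 in liver and brown fat, the duplication count 7 in cortex, and the reciprocal count 9 in cortex and 0 in cerebellum, striatum and liver. Interval genes called were 4, 5 and 0 in cerebellum, striatum and liver of deletion mice and 0 in cerebellum of duplication mice. In males only, the deletion count was 51 in cortex, 996 in liver, 0 in brown fat and 2 in white fat, the duplication count 2 in cortex and 7 in white fat, and the reciprocal count 1 in cortex, 1 in striatum and 0 in liver. Interval genes called were 4 and 7 in cerebellum and striatum of deletion mice and 0 in cerebellum of duplication mice. Each group held 2 mice of a sex. The deletion males include deletion 2, whose liver library stood apart (rank correlation 0.941, rest 0.974 to 0.975). In females of the deletion line, age goes with genotype. The sexes were not tested against each other, so the liver counts of 996 and 0 do not show a difference between them.

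Left out as standing apart were wild type 8 in cortex (long non-coding RNA share), wild types 2 and 5 and deletion 2 in cerebellum, deletion 2 in striatum and liver, wild types 1 and 2, duplication 2 and deletion 2 in brown fat, and wild type 1, duplication 1 and deletion 2 in white fat, a set chosen by rank correlation, transcript shares and markers. Without these libraries, the deletion count was 5 in cerebellum and 30 in liver, and the duplication count 3, 1 and 1 in cerebellum, striatum and white fat. The reciprocal count was 8, 4, 22 and 49 in cerebellum, striatum, liver and white fat, and the wild-type count 1, 0 and 48 in striatum, liver and white fat. Interval genes called were 24, 14 and 3 in striatum, liver and brown fat of deletion mice and 22, 11 and 6 in cerebellum, striatum and liver of duplication mice. The average over tissues then gave 3, 3 and 1 for the deletion, the reciprocal contrast and the wild types, the test between tissues 0 in deletion mice, and the correlation between lines was 0.019 in cerebellum, -0.019 in striatum and 0.349 in brown fat. Without the white fat libraries holding epididymis transcripts, the white fat counts were 2, 1 and 45 for the duplication, the reciprocal contrast and the wild types, and the correlation 0.226. Without both sets, white fat gave 3886, 2508 and 5103, with 9 interval genes called in duplication mice and a correlation of 0.098. That fit keeps only wild type 2 of the wild types of the duplication line, which is assumed to vary like the other groups, so these counts rest on 1 library.

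Over the brain tissues only, the average called 4, 1 and 2 genes for the deletion, the duplication and the reciprocal contrast. Among genes with a mean CPM of 1 or more in every tissue, the test between tissues called 1 gene in deletion mice. At an adjusted p under 0.1, 2 genes were called in at least 2 tissues of deletion mice. With an estimated correlation, 0 lists other than the interval were called in deletion mice and 1 in duplication mice, and fry called 0 and 5. By Spearman, the correlation between lines was -0.063, 0.272, -0.039, -0.133 and -0.127 in cortex, cerebellum, striatum, liver and brown fat. Over genes of mean log2 CPM of 3 or more it was -0.171, 0.367 and 0.179 in cortex, cerebellum and striatum, and over processed pseudogenes 0.547, 0.267, -0.078, -0.056, -0.229 and 0.079 in the 6 tissues in the order cortex, cerebellum, striatum, liver, brown fat and white fat.

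With each mouse left out in turn, the deletion count ranged from 147 to 407 in cortex, 1 to 3 in cerebellum, 4 to 30 in liver and 0 to 1 in brown fat, and the duplication count from 8 to 18 in cortex and 0 to 1 in white fat. The reciprocal count ranged from 20 to 208 in cortex, 1 to 3 in cerebellum, 1 to 4 in striatum, 3 to 22 in liver and 0 to 38 in white fat, and the wild-type count from 0 to 5 in cortex and 0 to 1 in liver. Interval genes called ranged from 12 to 24 in striatum and 4 to 14 in liver of deletion mice and from 0 to 2 in cerebellum of duplication mice. The average over tissues ranged from 1 to 3 for the deletion and 1 to 3 for the reciprocal contrast, and the test between tissues from 0 to 2 for the deletion and 0 to 3 for the duplication. The correlation between lines ranged from 0.066 to 0.151 in cortex, -0.114 to 0.247 in cerebellum, -0.041 to 0.184 in striatum, -0.569 to -0.1 in liver, -0.232 to 0.29 in brown fat and 0.307 to 0.674 in white fat. The mice behind many of these changes are named beside the counts in the results above. Those behind the ranges of the correlation and the cortex count of 407 are not.

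Wild types and duplication mice share the numbers 1 to 4. With the replicate block, the duplication count was 10 in striatum and 2 in liver, interval genes called were 0 in cerebellum and 7 in striatum, and 13 of the 41 cortex calls were kept. After group and sex were removed, the same-number correlations in cortex were -0.47, -0.07, -0.14 and -0.37, and 0 of the 8 cortex libraries correlated best with their own number. In brown fat the correlations were -0.17, 0.49, 0.34 and 0.28, with 1 of 8 best with its own number. Whether the numbers pair the mice is therefore left open, and they were not treated as pairs elsewhere.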

Other observations

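No test in this part was chosen to explain a result, and the values were looked at only after the data were seen. Some genes sorted the 16 mice into high and low classes that were the same in all 6 tissues, a pattern a sequence difference carried by the mouse would give. Of 15539 genes tested in every tissue, 10 did so with a gap of at least 2 on the log2 scale (pseudocount 0.1 CPM), namely the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y, the X-linked Gm27733 with the opposite classes, and Trim12a, Gdpd3, Gm16867, Gm27177 and the pseudogene Rpl34-ps2. Trim12a (chromosome 7, 104299894 to 104315455), a member of the TRIM family of antiviral factors, was high in 12 mice, which were all 8 of the deletion line, wild types 1 and 2 and duplication 2 and 4. Gdpd3, inside the interval, was high in 9 mice: 2 of 4 wild types and 4 of 4 carriers of the duplication line, and 1 of 4 wild types and 2 of 4 carriers of the deletion line. Its fitted changes in the 2 lines therefore follow these classes as well as the copy number. Gm16867 and Gm27177 on chromosome 14 were high in the same 13 mice.

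These classes also serve as a check on the labels. Gm16867 was high in wild type 3 and low in wild type 4, and high in duplication 1 and low in duplication 2, in every tissue. An exchange of these libraries in liver or white fat, where their spike-ins lay nearer to the other mix, would have broken those classes. The libraries labelled brown fat and white fat of wild type 1 are from the same mouse by their labels, so the classes say nothing about an exchange of that pair. Other tissues were also present in some samples by their leading genes. In striatum of deletion 2, a male, Xist stood at 79.9, the cerebellar gene Gabra6 at 34.7 and Alb at 82.8 CPM, against at most 9.3 for Xist in the other males and 2.03 and 3.42 for Gabra6 and Alb in the other 15 libraries. Xist stood at 12.7 CPM in cerebellum of wild type 5, a male. Albumin, Alb, stood at 91647 CPM in white fat of duplication 1 and at 485 or less in the other 15 white fat libraries, and the muscle myosin Myh4 ranged from 0.87 to 35230 CPM in brown fat.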
